A study of Mus musculus with 40 samples.

How the data were processed

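The series holds RNA-seq of 40 mouse mammary tumours from the MMTV-Wnt1 line, in which a transgene drives the Wnt1 ligand in the mammary gland. Tumours were wild-type, p53-null or p21-null, and were either untreated or taken from mice given doxorubicin, an anthracycline that poisons topoisomerase II and breaks DNA. Per the labels' protocols, doxorubicin was given intraperitoneally at 4 mg/kg daily for 5 days and tumours were harvested 24 h after the last dose, and RNA was extracted with Trizol from snap-frozen, pulverised tissue. Per the labels' protocols, wild-type libraries were made with the TruSeq Stranded Total RNA kit and libraries of both null genotypes with the TruSeq RNA v2 kit, so the kit and the genotype cannot be told apart between wild-type and null tumours.

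The authors deposited 1 table of transcript abundance in TPM per tumour. Per the submitters' processing notes, RSEM, whose version is not given in the sources used here, and the mouse build mm10 were used, and per the file names the gene models were those of Ensembl release 79 on GRCm38. The aligner and any trimming are not given in the sources used here. Each table held 43346 genes with TPM to 2 decimals, and its values summed to between 999998.9 and 1000001.0, so that the deposited TPM carry no information on sequencing depth and no counting interval can be given. No pair of tables held identical values (0 pairs). Gene identifiers were matched to GENCODE M21, an annotation of the same build, for symbols, biotypes and coordinates: 42462 matched and 884 did not.

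Groups and numbers were taken from the labels. Titles carry a number, and 6 numbers occur on 2 tumours of the same group (1475, 1556, 2493, 2551, 4116 and 4439). Because the other titles each carry a number of their own, tumours with the same number were taken as coming from 1 mouse and averaged on the log2 scale, which gave 34 mice. A mouse is named below by m and its number. Deviations from the group mean correlated between such tumours by -0.241, -0.345, -0.122, 0.001, 0.064 and 0.032, against medians of -0.236, -0.182, -0.182, -0.204, -0.233 and -0.117 for tumours of different numbers in the same groups. All 40 tumours were therefore also fitted as separate samples.

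TPM are not counts, so the values were analysed as log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with trended and robust empirical Bayes moderation. Genes with a TPM of at least 1 in at least 4 mice were kept, which left 16338. The 6 group means were fitted together, with 28 residual degrees of freedom, and contrasts were tested with Benjamini-Hochberg adjustment over all genes at an adjusted p of 0.05. Fold changes are on the log2(TPM + 1) scale and understate the change of genes with low TPM. This matters most in wild-type libraries, where TPM of protein-coding genes are lower because noncoding RNA fills most of the total. Values were therefore also computed after rescaling each tumour to the nuclear protein-coding genes (21461 identifiers), called the protein-coding scale, on which 14928 genes were tested. On that scale the median of all genes moved by over 0.1 log2 in 2 contrasts: to -0.389 from 1.879 for untreated p53-null minus wild-type, and to -0.424 from 1.893 for untreated p21-null minus wild-type.

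Lists of genes were fixed before the data were examined, as were the groups, the contrasts, the tests, the rule for naming genes and most alternatives. The 29 lists held 537 memberships, of which 536 matched a gene in the tables. They were p53 target genes, G2 and mitosis genes, G1/S and replication genes, senescence and secretory (SASP) genes, apoptosis regulators, phagocytosis and engulfment genes, lysosome genes, interferon-stimulated genes, MHC class I presentation genes, DNA repair genes, Wnt target genes, milk protein genes, replication-dependent histone genes, non-polyadenylated small RNA genes, mitochondrial genome genes, immediate early and heat shock genes, integrated stress and unfolded protein genes, and markers of luminal cells, basal cells, macrophages, neutrophils, T cells, NK cells, B cells, fibroblasts, endothelium, adipocytes, skeletal muscle and red blood cells. Several genes stand in more than 1 list. Lists were tested with limma's camera (preset correlation between genes of 0.01) with Benjamini-Hochberg adjustment over the 29 lists, and again with an estimated correlation, with fry, and by an exact permutation of the list mean over mice.

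Genes named in the text are Trp53, Cdkn1a and Wnt1, the 8 with the largest rise and the 8 with the largest fall past the threshold with a mean TPM of at least 5 in 1 group (leaving out predicted genes, pseudogenes and receptor segments), and up to 4 members per list with the smallest adjusted p. A gene named for any other reason is said to be chosen after its values were seen.

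The fit was tested on simulated data made from the 16338 genes, with 50 genes changed at each of 4 sizes. For genes lowered by 1 log2 unit it recovered 56% in the wild-type contrast, 70% in p53-null and 80% in p21-null, and for genes raised by 1 it recovered 68%, 62% and 90%. For genes lowered by 2 it recovered 90%, 76% and 90%, and for genes raised by 2 it recovered 98%, 94% and 96%. False calls were 6 of 162, 9 of 160 and 4 of 182. The simulated noise was normal and independent between genes, with 1 spread per gene for all 6 groups. Real groups differed in spread, with a median SD over mice of 0.158 to 0.293 log2, so these rates may not hold for the real calls.

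Alternatives were pseudocounts of 0.1 and 5, no filter on low values (32183 genes), a filter at TPM 5 (12387 genes), median-of-ratios scaling, quantile normalization, the protein-coding scale, all 40 tumours as samples with and without the title number as a random effect (estimated correlation 0.03), moderation without trend, only the groups compared, and each mouse left out in turn. Counts of called genes were set against other splits of the same mice, 100 splits with the real one included. For differences of responses, residuals of a fit of genotype and treatment without their interaction were shuffled over the mice of both genotypes instead. Single values were compared by exact permutation, or with 100000 resamples where groups were larger. Other work used python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Untreated null against untreated wild-type tumours are given only as counts because of the kit.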

Results

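Gene expression was measured by RNA-seq in 40 mammary tumours of MMTV-Wnt1 mice from 34 mice. The groups were wild-type untreated (6 tumours, 6 mice), wild-type doxorubicin (6 tumours, 5 mice), p53-null untreated (6 tumours, 4 mice), p53-null doxorubicin (6 tumours, 5 mice), p21-null untreated (6 tumours, 5 mice) and p21-null doxorubicin (10 tumours, 9 mice). The sequencing depth is unknown. Wild-type libraries, made with a total RNA kit, had 9.48% ± 0.89 (SD over tumours) of their TPM in nuclear protein-coding genes and 85.49% ± 3.82 in short noncoding RNA, and their 10 most abundant genes held 53.42% ± 1.63. In libraries of the null genotypes, made with the other kit, these shares were 83.94% ± 1.95, 0.26% ± 0.18 and 8.69% ± 1.34. Genes with TPM above 0 numbered 23447.42 ± 414.12 and 22894.21 ± 477.48.

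Trp53 (ENSMUSG00000059552, chromosome 11, 69580359 to 69591873, GRCm38) encodes p53, and Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727) encodes the cyclin-dependent kinase inhibitor p21, which p53 induces. Both were detected in the tumours labelled null for them. Trp53 stood at 61.1 ± 6.73 TPM (SD, n = 4) in untreated p53-null tumours and Cdkn1a at 51.0 ± 15.7 TPM (n = 5) in untreated p21-null tumours. The labels do not say which part of each gene the alleles lack, so gene-level TPM do not check the genotypes, and "p53-null" and "p21-null" are used as the labels give them. On the protein-coding scale Trp53 was at 92.4 ± 12.6 in untreated and 88.1 ± 11.9 in treated wild-type tumours (n = 6 and 5). It was at 73.8 ± 9.12 and 63.6 in p53-null (n = 4 and 5), and 117.8 and 99.8 in p21-null (n = 5 and 9). Trp53 did not pass the limma test for treatment in any genotype, with log2 fold changes of -0.10 ± 0.16 (SE), -0.27 ± 0.18 and -0.24 ± 0.15 and Benjamini-Hochberg adjusted p of at least 0.325. Cdkn1a rose from 35.3 ± 14.3 to 210.7 ± 26.5 in wild-type and from 60.0 ± 18.2 to 276.5 ± 35.9 in p21-null tumours on the protein-coding scale. In p53-null tumours its means were 44.2 and 59.1, and the log2 fold change of 0.35 ± 0.37 did not pass the limma test (Benjamini-Hochberg adjusted p = 0.715). Wnt1 (ENSMUSG00000022997, chromosome 15, 98789857 to 98793837), the ligand of the transgene, did not change past the threshold in any genotype, with log2 fold changes of 0.06 ± 0.29, 0.53 ± 0.32 and -0.32 ± 0.26 (limma, Benjamini-Hochberg adjusted p of at least 0.451).

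**Figure D1:**
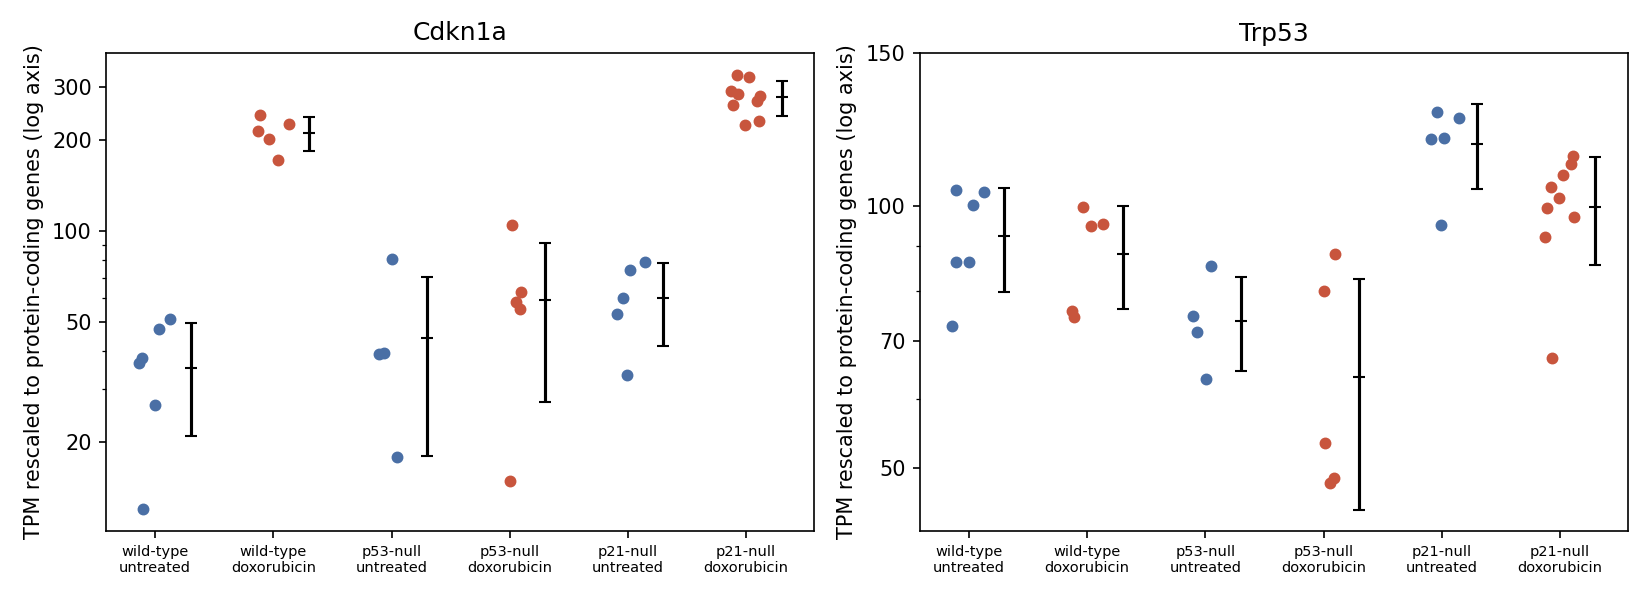
TPM of Cdkn1a and Trp53 after rescaling to protein-coding genes (log axis), with 1 point per mouse for the 6 groups (blue untreated, red doxorubicin); black marks show the mean ± SD. Treated wild-type and p21-null mice lie above all untreated mice of their genotype for Cdkn1a, with means of 210.7 and 276.5, while the 2 p53-null groups overlap, with means of 44.2 and 59.1.

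The design compares treated with untreated tumours within each genotype. In wild-type tumours, doxorubicin raised Cdkn1a by 2.29 ± 0.33 (log2 fold change ± SE, n = 5 treated and 6 untreated mice; limma with Benjamini-Hochberg adjustment, adjusted p = 5.01e-05; 2.66 ± 0.35 on the protein-coding scale). Other p53 targets rose with it, among them Ccng1, an atypical cyclin (1.92 ± 0.16), Eda2r, a receptor of the TNF receptor family (1.90 ± 0.18), and Bax, which permeabilises the outer mitochondrial membrane in apoptosis (1.18 ± 0.10). Interferon-stimulated genes also rose (7 of 30), and so did 2 of 17 macrophage and 5 of 30 lysosome genes, whose lists each had an adjusted p = 0.059 with an estimated correlation in limma's camera. Hemoglobin transcripts fell, with Hbb-bs at -4.39 ± 0.91 and Hba-a2 at -3.66 ± 0.81, and so did transcripts of replication-dependent histones, such as Hist1h3b at -1.92 ± 0.26. Each of these changes was seen in 5 of 5 treated mice when set against the untreated mean.

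In all, 180 of 16338 genes passed the threshold in wild-type tumours, 110 up and 70 down, of which 46 and 49 changed by at least 2-fold. After Cdkn1a, the largest rises were those of Cox6b2, a cytochrome c oxidase subunit best known from testis (1.99 ± 0.24; 2.97 ± 0.25 on the protein-coding scale), Ccng1, Eda2r and Ephx1, the microsomal epoxide hydrolase (1.91 ± 0.22). Next came Gas6, a ligand that bridges apoptotic cells to phagocytes (1.77 ± 0.34), Trp53inp1, a p53-induced nuclear protein (1.71 ± 0.23), and Psrc1, a microtubule-associated protein (1.66 ± 0.21). The largest falls were those of Hbb-bs, Hba-a2, Hbb-bt (-2.46 ± 0.62) and the histones Hist1h2ai (-2.28 ± 0.48), Hist1h2ap (-2.05 ± 0.43), Hist1h2ab (-1.97 ± 0.27), Hist1h3b and Hist1h3c (-1.91 ± 0.35). Hemoglobin and histone genes have near-identical copies, so the split of reads among them is uncertain.

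Of 39 measured p53 target genes, 20 rose, 0 fell and 19 did not pass (28 rose when adjusted over the list alone, and 28 on the protein-coding scale). Ei24, which responds to etoposide and p53, was among those that rose (0.87 ± 0.09). The list stood above other genes by limma's camera (Benjamini-Hochberg adjusted p = 3.14e-71, and adjusted p = 1.36e-06 with an estimated correlation). Of 30 interferon-stimulated genes, 7 rose and 23 did not pass (26 rose when adjusted over the list alone), and on the protein-coding scale 25 of 29 rose, with a median of 1.42 against 0.83 as deposited. They included Ifit3 (1.53 ± 0.31), the transcription factor Irf7 (1.62 ± 0.34), Oasl2 (1.64 ± 0.35) and Bst2 (1.35 ± 0.31). Camera gave the interferon list an adjusted p of 1.31e-36 (limma, Benjamini-Hochberg), and an adjusted p = 0.0317 with an estimated correlation. In the MHC class I list 2 of 12 genes rose, the peptide transporter Tap1 (0.93 ± 0.19) and B2m (0.83 ± 0.21), with 7 when adjusted over the list alone. Limma's camera gave it a Benjamini-Hochberg adjusted p = 1.45e-13, and adjusted p = 0.059 with an estimated correlation.

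Macrophage markers gave 2 rises among 17 genes, Cd68 (1.16 ± 0.24) and the complement component C1qa (1.10 ± 0.26), or 9 when adjusted over the list alone. Lysosome genes gave 5 of 30, including the cathepsins Ctsb (0.78 ± 0.16) and Ctsd (0.76 ± 0.17) and the protease Lgmn (0.89 ± 0.22), or 11 when adjusted over the list alone. Phagocytosis genes gave 2 of 27, Gas6 and C1qa, or 8 when adjusted over the list alone. Limma's camera put these lists up with Benjamini-Hochberg adjusted p of 6.67e-15, 2.75e-16 and 3.5e-12, and with an estimated correlation each had an adjusted p = 0.059. Among senescence and SASP genes 1 of 31 rose, the macrophage growth factor Csf1 (0.74 ± 0.16; 1 when adjusted over the list alone). The growth factor Areg was at -2.08 ± 0.79 without passing. Limma's camera gave the list a Benjamini-Hochberg adjusted p = 0.000456, and adjusted p = 0.32 with an estimated correlation. The integrated stress list gave 1 of 12, Sesn2, which p53 also induces (1.13 ± 0.14; camera adjusted p = 0.0293, and adjusted p = 0.32 with an estimated correlation).

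Of 18 replication-dependent histone genes 17 fell (18 when adjusted over the list alone), with a list median of -1.52 (limma's camera, Benjamini-Hochberg adjusted p = 2.96e-61, and adjusted p = 0.000158 with an estimated correlation). Of 5 red blood cell genes 3 fell (4 when adjusted over the list alone), with a median of -2.46 (camera adjusted p = 3.8e-09, and adjusted p = 0.0317 with an estimated correlation). No single gene of the G1/S or of the G2 and mitosis list passed (8 and 1 fell when adjusted over each list alone), and Mki67, a marker of cycling cells, was at -1.14 ± 0.33. Their medians were -0.44 and -0.54 (limma's camera, Benjamini-Hochberg adjusted p = 3.95e-17 and 5.81e-15; adjusted p = 0.148 and adjusted p = 0.238 with an estimated correlation). DNA repair genes (30, none past) and mitochondrial genome genes (13, none past) lay lower as sets by camera, with adjusted p = 0.000124 and 0.013, and adjusted p = 0.41 and adjusted p = 0.336 with an estimated correlation. Basal, adipocyte and muscle markers lay higher as sets without a single gene past the threshold (10, 11 and 14 genes), with the basal keratin Krt5 at 1.06 ± 0.40. Their adjusted p from limma's camera were 0.0141, 0.00172 and 0.03 (adjusted p = 0.238, adjusted p = 0.299 and adjusted p = 0.677 with an estimated correlation). Neither camera nor any single gene called apoptosis regulators (adjusted p = 0.623), Wnt targets (0.655), luminal markers (0.122), milk proteins (0.675), small RNAs (0.0549) or immediate early genes (0.623). The same held for neutrophil (0.0609), T cell (0.689), NK (0.675), B cell (0.689), fibroblast (0.122) and endothelial markers (0.107). With other scaling the wild-type count was larger and its balance moved: 557 up and 199 down on the protein-coding scale, and 456 up and 503 down with median-of-ratios scaling. Of 33 named calls in wild-type tumours, 8 were lost when some single mouse was left out (B2m, Bst2, C1qa, Ctsd, Hba-a2, Hbb-bt, Lgmn and Oasl2).

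In p53-null tumours doxorubicin raised interferon-stimulated genes in the fit of all groups (n = 5 treated and 4 untreated mice). With only these groups fitted none of them passed alone, and limma's fry gave their list an adjusted p = 0.101. Ifit1 rose by 2.39 ± 0.40 (log2 fold change ± SE; limma with Benjamini-Hochberg adjustment, adjusted p = 0.000554) and Ifit3 by 2.33 ± 0.34. Oas3, which senses double-stranded RNA, rose by 2.30 ± 0.34, and Rsad2, the antiviral protein viperin, by 2.22 ± 0.36. Hemoglobin transcripts fell, with Hbb-bs at -4.42 ± 1.01 and Hba-a2 at -4.41 ± 0.90. None of the 39 p53 target genes passed the threshold, and Cdkn1a stood at 0.35 ± 0.37, Ccng1 at 0.47 ± 0.18, Trp53inp1 at 0.77 ± 0.26 and Ddit4l at 1.09 ± 0.31.

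The threshold was passed by 330 genes, 231 up and 99 down, of which 136 and 19 changed by at least 2-fold. The excess of rises depended on the mice and the setting: it was 283 up and 264 down without treated m2688, 408 and 91 without treated m2769, and 283 and 215 with a pseudocount of 5. The remaining largest rises were Ifit3b (2.36 ± 0.35), whose near-identical copy Ifit3 makes it uncertain, Ifi44 (2.22 ± 0.44), Ms4a4c (2.18 ± 0.38) and Irf7 (2.09 ± 0.37). The other largest falls were Hbb-bt (-4.10 ± 0.69), Hba-a1 (-3.40 ± 0.83), Hmga1b (-3.84 ± 0.69), which shares reads with Hmga1 and is uncertain, and Dpysl5, a neuronal phosphoprotein (-1.86 ± 0.33). Cnmd, a cartilage glycoprotein, fell too (-1.52 ± 0.38), and Mir8115, at a mean of 31.62 TPM in untreated tumours, was listed at 0 in all treated ones. On the protein-coding scale Hmga1b and Cnmd did not pass (limma, Benjamini-Hochberg adjusted p = 0.0586 and 0.123).

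In the fit of all groups, all 30 interferon-stimulated genes rose (30 when adjusted over the list alone), with a median of 1.75; Mx1 (2.09 ± 0.30), Stat2 (1.58 ± 0.23) and Trim30a (1.82 ± 0.26) had the smallest adjusted p beside Ifit3. Limma's camera gave a Benjamini-Hochberg adjusted p of 5.8e-51, and an adjusted p = 0.0257 with an estimated correlation. In the MHC class I list 3 of 12 genes rose, H2-T23 (0.90 ± 0.21), the immunoproteasome subunit Psmb10 (0.85 ± 0.20, in 4 of 5 mice) and B2m (0.95 ± 0.23), or 11 when adjusted over the list alone. The adjusted p (limma's camera, Benjamini-Hochberg) was 9.76e-10, and adjusted p = 0.282 with an estimated correlation. Among SASP genes 1 of 31 rose, the T cell chemoattractant Cxcl10 (1.71 ± 0.28), or 4 when adjusted over the list alone (camera adjusted p = 0.000367, and adjusted p = 0.606 with an estimated correlation). Of 8 NK and cytotoxic markers 1 rose, granzyme Gzmb (1.73 ± 0.43), or 4 when adjusted over the list alone (camera adjusted p = 0.000265, and adjusted p = 0.589 with an estimated correlation). Of 11 adipocyte markers 1 rose, adiponectin Adipoq (1.67 ± 0.46), or 5 when adjusted over the list alone (camera adjusted p = 0.000138, and adjusted p = 0.386 with an estimated correlation). Adipoq passed only as deposited (limma, Benjamini-Hochberg adjusted p = 0.0491 against 0.064 on the protein-coding scale). T cell markers lay higher as a set (11 genes, none past; camera adjusted p = 0.0206, and adjusted p = 0.924 with an estimated correlation). G1/S genes lay lower (30 genes, none past, median -0.15; adjusted p = 0.016, and adjusted p = 0.962 with an estimated correlation).

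Of 5 red blood cell genes 4 fell in p53-null tumours (5 when adjusted over the list alone), with a median of -4.10 (limma's camera, Benjamini-Hochberg adjusted p = 9.76e-10, and adjusted p = 0.0378 with an estimated correlation). In lists that camera did not call, the death ligand Tnfsf10 (1.27 ± 0.26) and Birc3, an inhibitor of apoptosis (0.62 ± 0.17), rose among 22 apoptosis regulators (adjusted p = 0.289; 2 up and 1 down when adjusted over the list alone). The engulfment receptor Megf10 fell (-0.84 ± 0.19) among 27 phagocytosis genes (0.467; 1 down when adjusted over the list alone), and Egr2 fell (-1.41 ± 0.32) among 15 immediate early genes (0.921). Neither camera nor any single gene called p53 targets (0.899; 0 when adjusted over the list alone), G2 and mitosis genes (0.899), lysosome genes (0.106), DNA repair genes (0.572), Wnt targets (0.572), milk proteins (0.572), histones (0.0878), small RNAs (0.732), mitochondrial genes (0.088) or stress genes (0.732). The same held for markers of luminal (0.899) and basal cells (0.235), macrophages (0.0878), neutrophils (0.1), B cells (0.0614), fibroblasts (0.756), endothelium (0.921) and muscle (0.899). These gene calls rest on the fit of all groups. With only the groups compared in the limma fit, 1 gene passed (1332 at an unadjusted p under 0.05), and 13 of 100 splits of the 9 mice, the real one included, gave as many calls. The count was 209 without untreated mouse m2119, 166 without untreated m881, 185 without treated m2237, 547 without treated m2688, 499 without treated m2769 and 184 without treated m2771. Of 29 named calls, 12 were lost when some single mouse was left out (Adipoq, B2m, Birc3, Cnmd, Gzmb, H2-T23, Hba-a1, Hbb-bs, Megf10, Mir8115, Psmb10 and Tnfsf10). With only the groups compared in the limma fit, 0 of the 29 passed.

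In p21-null tumours doxorubicin raised p53 targets and interferon-stimulated genes (n = 9 treated and 5 untreated mice). Lists of macrophage, neutrophil, T cell and NK markers stood higher by limma's camera but each had an adjusted p = 0.111 with an estimated correlation. Cdkn1a rose by 2.24 ± 0.30 (log2 fold change ± SE; limma with Benjamini-Hochberg adjustment, adjusted p = 3.8e-06), Gdf15, a stress-induced cytokine, by 2.78 ± 0.15, Ifit3 by 3.10 ± 0.28 and Cxcl10 by 2.74 ± 0.23. Hemoglobin transcripts fell, from 1562 to 4.40 mean TPM for Hbb-bs (-7.95 ± 0.84). Each was seen in 9 of 9 treated mice.

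The threshold was passed by 1537 genes, 891 up and 646 down, of which 369 and 60 changed by at least 2-fold. The balance of directions was not stable: it was 779 up and 848 down with all 40 tumours, 716 and 828 without untreated m4555, 852 and 886 without treated m4183, and 819 and 942 without treated m4380. The largest rises were those of Sncg, gamma-synuclein (3.88 ± 0.37), Cox6b2 (3.28 ± 0.22), Ifit3, the basal keratin Krt15 (2.81 ± 0.62), Gdf15, Ifit1 (2.77 ± 0.33), Cxcl10 and S100a9, a calcium-binding protein of neutrophils (2.71 ± 0.76). The largest falls beside Hbb-bs were Hbb-bt (-7.31 ± 0.57), Hba-a2 (-7.18 ± 0.74), Hba-a1 (-5.39 ± 0.69) and Alas2, the erythroid enzyme of heme synthesis (-2.34 ± 0.30). Further falls were those of Snorc, a cartilage proteoglycan (-2.28 ± 0.60), Lbhd2 (-2.01 ± 0.53) and the homeobox factor Meox1 (-1.85 ± 0.34). The count was 1011 without untreated mouse m4536 and 1006 without untreated mouse m4539. Of 60 named calls, 18 were lost when some single mouse was left out, among them S100a9, Mmp8, Csf3r, Cd8a, Adipoq, Lpl, Cd22, Tnfsf10, Casp6, Nr4a1, Egr2, Rn7sk and Lbhd2.

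Of 39 p53 target genes 27 rose in p21-null tumours, 0 fell and 12 did not pass (31 rose when adjusted over the list alone), with Ccng1 at 2.21 ± 0.15, Eda2r at 2.46 ± 0.17 and Bax at 1.34 ± 0.10. Limma's camera gave the list a Benjamini-Hochberg adjusted p = 1.27e-50, and adjusted p = 3.09e-05 with an estimated correlation. Of 30 interferon-stimulated genes 29 rose (30 when adjusted over the list alone), with a median of 2.01, among them Mx1 (2.71 ± 0.24) and the nucleic acid sensor Zbp1 (2.18 ± 0.23). Camera gave them an adjusted p = 2.93e-56 (limma, Benjamini-Hochberg), and adjusted p = 0.00516 with an estimated correlation. All 12 MHC class I genes rose (12 when adjusted over the list alone), including Tap1 (1.48 ± 0.17) and B2m (1.41 ± 0.19) (camera adjusted p = 1.1e-20, and adjusted p = 0.0149 with an estimated correlation).

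Macrophage markers rose in 9 of 17 cases (11 when adjusted over the list alone), including Ms4a7 (1.60 ± 0.26), C1qa (1.22 ± 0.24) and the Fc receptor Fcgr1 (1.60 ± 0.25). Phagocytosis genes rose in 10 of 27 cases (13 up and 2 down when adjusted over the list alone), with Fcgr4 at 1.91 ± 0.27. Lysosome genes rose in 11 of 30 (16 when adjusted over the list alone), with Cd68 at 1.28 ± 0.22, Ctsb at 0.83 ± 0.15 and Ctss at 1.43 ± 0.29. Neutrophil markers rose in 4 of 9 cases (8 when adjusted over the list alone), with Mmp8 at 0.82 ± 0.24 and the receptor Csf3r at 0.87 ± 0.25. T cell markers rose in 6 of 11 cases (9 when adjusted over the list alone), with Cd3d at 1.03 ± 0.26 and Cd8a at 0.70 ± 0.19. NK markers rose in 4 of 8 (7 when adjusted over the list alone), with Nkg7 at 1.39 ± 0.29 and Klrk1 at 1.14 ± 0.27. SASP genes gave 12 rises and 1 fall among 31 (16 and 1 when adjusted over the list alone), including the chemokines Ccl5 (1.98 ± 0.31), Ccl7 (1.73 ± 0.33) and Cxcl2 (1.63 ± 0.33). Adipocyte markers gave 2 of 11, Adipoq (1.38 ± 0.38) and Lpl (0.96 ± 0.30, in 7 of 9 mice), or 7 when adjusted over the list alone. Limma's camera put these lists up with Benjamini-Hochberg adjusted p of 6.25e-13 (macrophage), 1.8e-07 (phagocytosis), 3.96e-12 (lysosome), 9.64e-07 (neutrophil), 2.24e-07 (T cell), 8.53e-07 (NK), 2.16e-09 (SASP) and 1.16e-05 (adipocyte). With an estimated correlation phagocytosis had an adjusted p = 0.128 and the other 7 lists had an adjusted p = 0.111.

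All 5 red blood cell genes fell in p21-null tumours (5 when adjusted over the list alone; limma's camera, Benjamini-Hochberg adjusted p = 1.08e-13, and adjusted p = 0.00516 with an estimated correlation). Of 18 histone genes Hist1h4b alone fell (-1.20 ± 0.27; 1 when adjusted over the list alone), with a list median of -0.40 (camera adjusted p = 0.0471, and adjusted p = 0.823 with an estimated correlation). Of 6 B cell markers Cd22 rose (0.74 ± 0.23; 1 when adjusted over the list alone; camera adjusted p = 0.0336, and adjusted p = 0.616 with an estimated correlation). In lists that camera did not call, single genes moved. Tnfsf10 rose (0.79 ± 0.22) and Casp6 fell (-0.35 ± 0.10) among apoptosis regulators (adjusted p = 0.337). Rnf43, a membrane ubiquitin ligase that damps Wnt signalling, fell among Wnt targets (-0.68 ± 0.16, camera adjusted p = 0.137), and Rn7sk rose among small RNAs (0.73 ± 0.21, camera adjusted p = 0.356). Short noncoding RNA held 0.12% to 0.95% of TPM in treated and 0.14% to 0.21% in untreated p21-null libraries, so for Rn7sk an effect of library preparation is not excluded. Nr4a1 (-0.69 ± 0.17) and Egr2 (-0.95 ± 0.26) fell among immediate early genes (0.356), and Sesn2 rose (1.27 ± 0.13) among stress genes (0.586). Neither camera nor any single gene called G2 and mitosis genes (0.0662), G1/S genes (0.0662), DNA repair (0.654), luminal (0.494), basal (0.399), milk (0.68), fibroblast (0.991), endothelial (0.423), muscle (0.183) or mitochondrial genes (0.641). Across the 3 treatment comparisons the direction given by camera and the sign of the list median differed for a few lists, none of which camera called. They were B cell markers in wild-type, G2 and mitosis and DNA repair genes in p53-null, and apoptosis regulators, fibroblast, mitochondrial and stress genes in p21-null tumours.

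**Figure D2:**
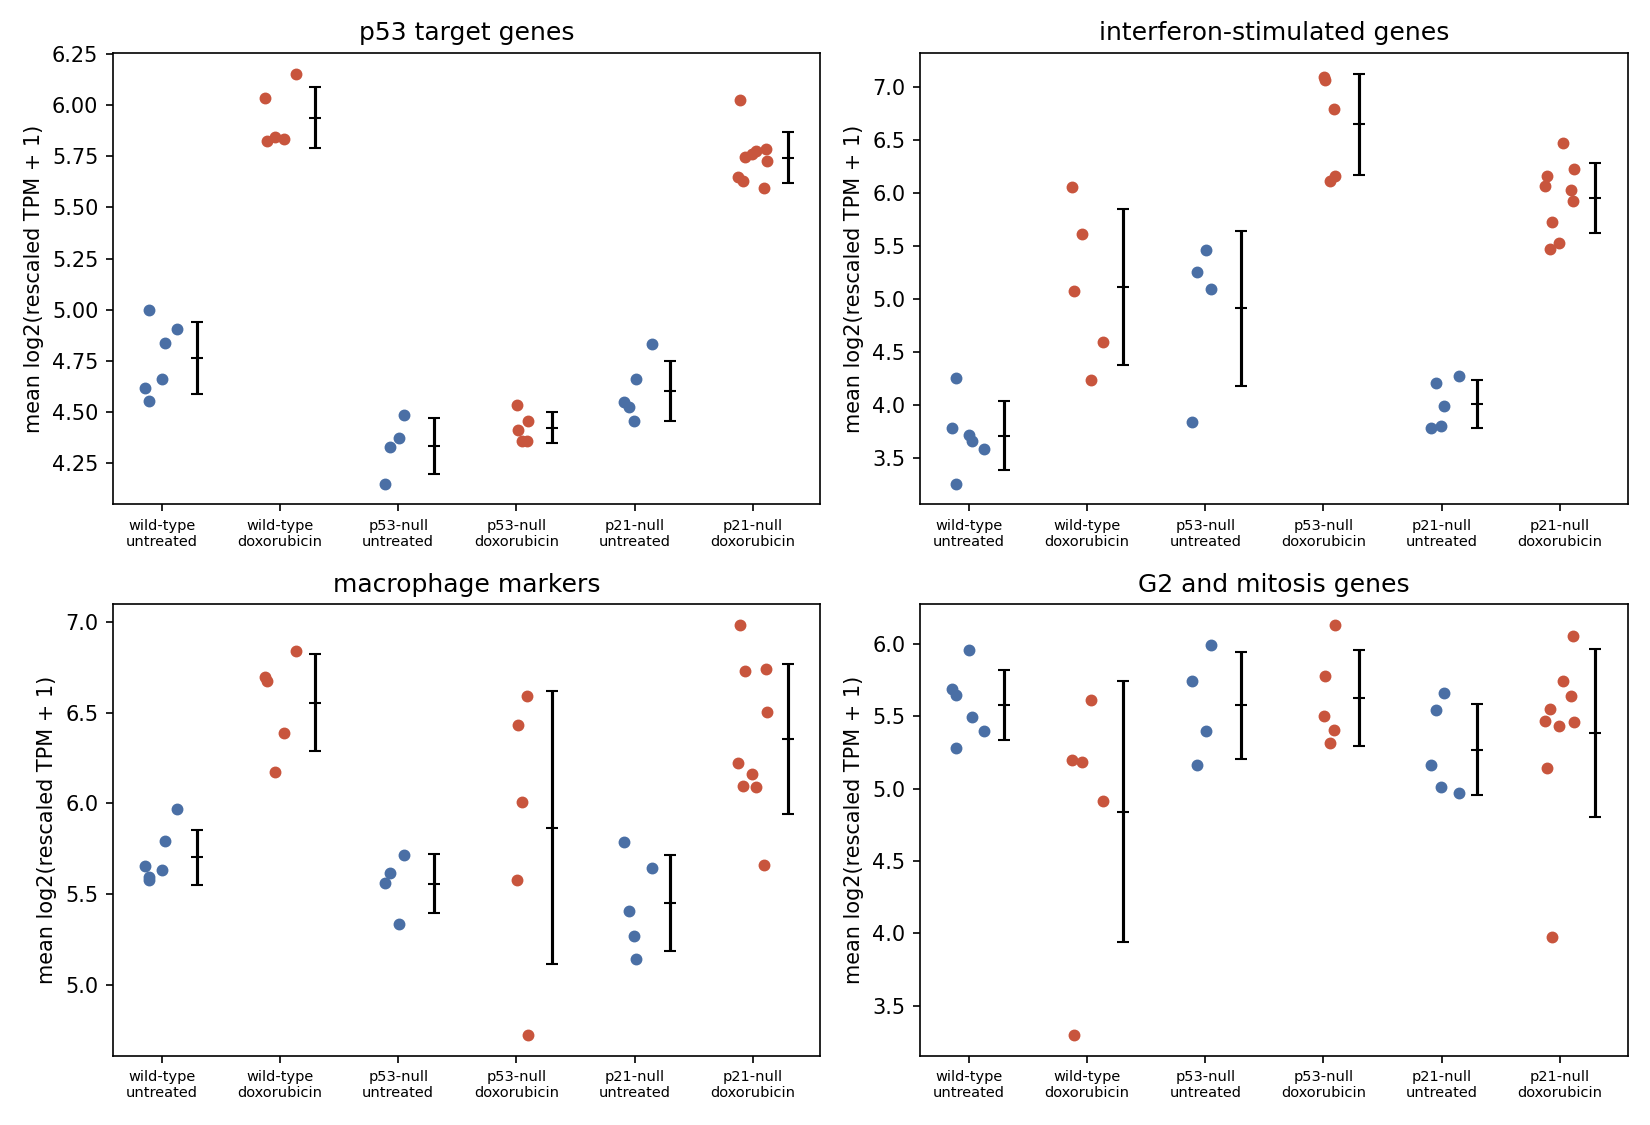
Mean log2(rescaled TPM + 1) over the genes of 4 lists, with 1 point per mouse for the 6 groups (blue untreated, red doxorubicin), black marks for the mean ± SD and vertical axes that do not start at 0. On this scale the median log2 change with doxorubicin for p53 targets was 1.18, 1.05 and 0.07 in wild-type, p21-null and p53-null tumours, and 1.42, 2.02 and 1.81 for interferon-stimulated genes.

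The treatment effects were then set against each other between genotypes. The rise of p53 targets was smaller in p53-null than in wild-type tumours for 13 of 39 genes (23 when adjusted over the list alone). The differences were -1.46 ± 0.16 for Bax (limma with Benjamini-Hochberg adjustment, adjusted p = 1.09e-06), -1.77 ± 0.27 for Eda2r and -1.27 ± 0.19 for Bbc3, a BH3-only activator of apoptosis. For Cdkn1a the difference was -1.94 ± 0.50 and did not pass as deposited (limma, Benjamini-Hochberg adjusted p = 0.0942), while on the protein-coding scale it was -2.29 ± 0.52 and passed (0.0227). Histone transcripts showed the opposite sign, with 4 of 18 past the threshold (17 when adjusted over the list alone). Untreated null tumours hold these transcripts at a median of 1.48 and 1.5 on the protein-coding scale, against 307 in wild-type, and a fall there is hard to see on the log2(TPM + 1) scale. In all, 60 genes differed, 23 up and 37 down, against 77 up and 25 down with a pseudocount of 5. The largest negative differences were Cox6b2 (-3.30 ± 0.36), Sncg (-2.76 ± 0.60), Ephx1 (-2.07 ± 0.32), Psrc1 (-2.0 ± 0.31), Dpysl5 (-1.92 ± 0.45), Serpine2, a protease inhibitor (-1.88 ± 0.39), Cpt1c (-1.86 ± 0.29) and Eda2r. The largest positive ones were 7 histone genes, among them Hist1h2an (1.91 ± 0.42) and Hist1h2ac (1.85 ± 0.40), and Ifit1bl1 (1.59 ± 0.34), which was at 0.69 ± 0.41 on the protein-coding scale and did not pass there. Camera called the p53 list down (limma, Benjamini-Hochberg adjusted p = 1.14e-35, and adjusted p = 0.000453 with an estimated correlation) and the histone list up (adjusted p = 1.41e-23, and adjusted p = 0.0401 with an estimated correlation). Its call for interferon-stimulated genes (up, 0 past, median 0.75, adjusted p = 1.53e-11) had an adjusted p = 0.559 with an estimated correlation. On the protein-coding scale 27 genes differed up and 84 down, and the count was 26 without treated wild-type mouse m1475 and 37 without treated p53-null mouse m2237.

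Between p21-null and wild-type tumours the response of Cdkn1a differed by -0.05 ± 0.45 (limma, Benjamini-Hochberg adjusted p = 0.984). Genes with a larger rise in p21-null tumours included Gdf15 (2.27 ± 0.22), the guidance receptor Robo3 (2.23 ± 0.23), Cxcl10 (2.22 ± 0.34) and Ms4a4c (2.30 ± 0.46). Others were Ifit1bl1 (2.16 ± 0.31), Slfn4 (2.16 ± 0.47) and Mx1 (2.07 ± 0.36), while Hbb-bt (-4.85 ± 0.84) and Alas2 (-2.03 ± 0.45) differed the other way. These 9 did not pass on the protein-coding scale, where the differences were 0.90 ± 0.29 for Gdf15, 1.47 ± 0.42 for Cxcl10, 1.17 ± 0.44 for Mx1 and -2.63 ± 0.92 for Hbb-bt. In all 65 genes differed, 63 up and 2 down, against 9 up and 3 down on the protein-coding scale and 67 up and 11 down with median-of-ratios scaling. Of the histone list 6 of 18 differed upward (13 when adjusted over the list alone), and Hist2h2ab (0.70 ± 0.12), Hist1h4a (1.96 ± 0.37), Hist1h3b (1.86 ± 0.36) and Hist2h3b (1.59 ± 0.33) also passed on the protein-coding scale. Here too the low level in null tumours leaves little room for a fall. Limma's camera called histones (Benjamini-Hochberg adjusted p = 5.29e-28, and adjusted p = 0.0337 with an estimated correlation) and red blood cell genes (2 of 5 down, 5 when adjusted over the list alone; adjusted p = 4.08e-10, and adjusted p = 0.0337 with an estimated correlation). The p53 list gave 2 of 39 up (5 when adjusted over the list alone; adjusted p = 6.44e-08, and adjusted p = 0.149 with an estimated correlation; 0.422 on the protein-coding scale), with Pmaip1, a BH3-only protein, at 1.33 ± 0.30 (0.53 ± 0.36 on the protein-coding scale, where it did not pass). The interferon list gave 2 of 30 (21 when adjusted over the list alone; adjusted p = 9.89e-29, and adjusted p = 0.0922 with an estimated correlation). The count was 42 without untreated wild-type mouse m1198 and 38 without untreated p21-null mouse m4555.

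The 2 null genotypes share a library kit. Of 39 p53 target genes 23 rose more in p21-null than in p53-null tumours (26 when adjusted over the list alone, 19 on the protein-coding scale), with Gdf15 at 2.66 ± 0.23, Bbc3 at 1.92 ± 0.18 and Bax at 1.62 ± 0.15. For the list, limma's camera gave a Benjamini-Hochberg adjusted p = 2.82e-48, and adjusted p = 4.36e-05 with an estimated correlation. Cdkn1a differed by 1.89 ± 0.48, past the threshold as deposited (limma, Benjamini-Hochberg adjusted p = 0.045) but not on the protein-coding scale (0.087). In all 153 genes differed, 124 up and 29 down (94 up and 9 down on the protein-coding scale). Single mice moved the falls: the split was 136 and 92 without treated p53-null m2551, 132 and 73 without untreated p53-null m2493, and 126 and 64 or 131 and 59 without treated p21-null m4380 or m4183. The largest differences were Sncg (4.84 ± 0.58), Cox6b2 (4.58 ± 0.35), Hmga1b (3.89 ± 0.90, uncertain, and not past on the protein-coding scale), Gdf15 and Robo3 (2.46 ± 0.25). Next were the phosphatase Ptp4a3 (2.36 ± 0.27), Eda2r (2.33 ± 0.26) and Inka2 (2.31 ± 0.24). In the other direction they were Sox14 (-2.01 ± 0.48), the adaptor Grb10 (-1.65 ± 0.37), Dlx5 (-1.42 ± 0.33), Zfp395 (-1.21 ± 0.29), Dpp4 (-1.16 ± 0.27) and Zdhhc2 (-0.99 ± 0.22). Of the other lists, Sesn2 alone passed as a single gene (1.10 ± 0.20, stress genes). Of 18 named calls, 8 were lost when some single mouse was left out (Cdkn1a, Dlx5, Dpp4, Grb10, Hmga1b, Sox14, Zdhhc2 and Zfp395), against 10 of 21 for p53-null minus wild-type (among them Dpysl5, Serpine2, Sesn2, Sncg and Ifit1bl1) and 4 of 15 for p21-null minus wild-type (Alas2, Hist1h2ah, Pmaip1 and Slfn4). With a pseudocount of 0.1, 12 of 18, 11 of 21 and 2 of 15 named calls of these comparisons still passed, and with only the groups compared 11 of 18, 10 of 21 and 15 of 15 did. Camera's calls for macrophage markers (median 0.72, adjusted p = 4.41e-06), interferon-stimulated genes (0.34, adjusted p = 0.0097) and red blood cell genes (-2.78, adjusted p = 0.00136) had adjusted p = 0.752, adjusted p = 0.946 and adjusted p = 0.752 with an estimated correlation.

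Calls overlapped between genotypes, in comparisons that share no libraries but take the same estimate of the spread per gene from 1 fit. A gene with a small spread is thus called more easily in each, and the number for independent lists is only a rough baseline. Wild-type and p21-null tumours shared 104 rises, where 6.00 would be shared by independent lists, and 13 falls (2.77). Wild-type and p53-null tumours shared 19 rises (1.56) and 3 falls (0.424), and p53-null and p21-null tumours shared 164 rises (12.6) and 19 falls (3.91). The 19 genes raised in all 3 genotypes included 7 of the interferon list, such as Stat2, Irf7 and Ifit3, and 0 of the p53 list, and the 3 genes lowered in all were Hba-a2, Hbb-bs and Hbb-bt. On the protein-coding scale 82 genes were raised in all 3 genotypes, 25 of them in the interferon list, and 7 were lowered. Log2 fold changes correlated across the 16338 genes, which are not independent replicates, with Pearson r of 0.30, 0.52 and 0.36 and Spearman rho of 0.21, 0.43 and 0.25 for wild-type with p53-null, wild-type with p21-null and p53-null with p21-null. Of the 891 rises in p21-null tumours, 117 were larger than in p53-null tumours by the test of the difference, 23 of them p53 targets. For 774 the difference did not pass, and 0 were smaller. Of the 110 rises in wild-type tumours 30 were larger, 13 of them p53 targets, for 80 the difference did not pass, and 0 were smaller. These genes were chosen for a rise in the same mice that enter the test. That choice favours a larger effect in the genotype they were chosen in, so the absence of smaller ones says little.

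Among untreated tumours, p53-null and p21-null differed in 6 of 30 interferon-stimulated, 5 of 12 MHC class I and 8 of 39 p53 target genes (n = 4 and 5 mice). Each of these lists had an adjusted p = 0.511 with an estimated correlation in limma's camera. Cxcl10 was higher in p53-null tumours by 1.70 ± 0.28 (log2 fold change ± SE; limma with Benjamini-Hochberg adjustment, adjusted p = 0.000312), Ccl5 by 1.77 ± 0.37, Ifit3 by 1.70 ± 0.34 and B2m by 0.98 ± 0.23. Ccng1 (-1.17 ± 0.18), Eda2r (-1.26 ± 0.20), Bax (-0.61 ± 0.12) and Gdf15 (-0.84 ± 0.18) were lower. So was Trp53 (-0.70 ± 0.18; limma, Benjamini-Hochberg adjusted p = 0.022), while Cdkn1a (-0.60 ± 0.37) and Wnt1 (-0.18 ± 0.32) did not pass. Each gene called here differed in the same direction in 4 of 4 p53-null mice when set against the p21-null mean.

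In all 491 genes differed, 244 higher and 247 lower in p53-null tumours, 100 and 62 of them by at least 2-fold. The largest differences upward were Eno1b (6.43 ± 1.59) and Rnps1 (2.56 ± 0.26), both uncertain because of near-identical copies, and the caseins Csn2 (3.99 ± 0.94) and Csn1s2a (3.73 ± 0.83). They were followed by the secreted proteins Sbp (2.88 ± 0.67) and Dcpp3 (2.61 ± 0.65), the matrix proteoglycan Bcan (2.51 ± 0.57) and Scube3 (2.38 ± 0.43). Downward they were BC018473 (-5.21 ± 1.25), the small GTPase Rab44 (-3.65 ± 0.16, from 21.1 to 0.741 mean TPM), Xlr4c (-2.47 ± 0.59) and Pamr1 (-2.45 ± 0.53). After these came Npw, a neuropeptide precursor (-2.14 ± 0.31), Snora57 (-1.75 ± 0.39), and Tnfsf13os (-2.32 ± 0.22) and Slmapos2 (-1.71 ± 0.25), which overlap genes on the other strand and are uncertain. Eno1b did not pass on the protein-coding scale (limma, Benjamini-Hochberg adjusted p = 0.0554).

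Of 30 interferon-stimulated genes 6 were higher in untreated p53-null tumours (20 when adjusted over the list alone, 3 on the protein-coding scale), and of 12 MHC class I genes 5 were higher (9 when adjusted over the list alone), among them Tapbp (0.89 ± 0.20). Of 39 p53 targets 8 were lower (12 lower and 1 higher when adjusted over the list alone, 4 lower on the protein-coding scale). Limma's camera gave these lists Benjamini-Hochberg adjusted p of 4.11e-15, 3.24e-07 and 4.42e-05, and each had an adjusted p = 0.511 with an estimated correlation. Called genes were frequent in the stretch around Cdkn1a (see the last part). How many of the MHC class I genes lie in that stretch was not tabulated. Their difference can therefore not be separated from one of DNA linked to the targeted allele. Camera also called 3 lists that each had an adjusted p = 0.511 with an estimated correlation. T cell markers were up (1 of 11, the kinase Lck at 1.20 ± 0.25; 2 when adjusted over the list alone; limma's camera, adjusted p = 0.00012). Small RNAs were up by limma's camera (adjusted p = 0.0266), with 3 of 8 genes past the threshold, or 3 up and 1 down when adjusted over the list alone. The 3 were Rmrp at 2.03 ± 0.37, Rn7sk at 1.71 ± 0.26 and Rpph1 at 1.49 ± 0.37. Short noncoding RNA held only 0.31% and 0.16% of TPM in these p53-null and p21-null libraries, so an effect of library preparation is not excluded. Red blood cell genes were down (0 of 5, 5 when adjusted over the list alone, median -1.94; adjusted p = 0.00167). Milk proteins were up (2 of 7, Csn2 and Csn1s2a; camera adjusted p = 0.0053, and adjusted p = 0.554 with an estimated correlation). Fibroblast genes were up (1 of 18, Fap at 1.03 ± 0.25; 5 when adjusted over the list alone; adjusted p = 0.00273, and adjusted p = 0.832 with an estimated correlation). G2 and mitosis genes lay higher (0 of 30; adjusted p = 0.0098, and adjusted p = 0.977 with an estimated correlation) and luminal markers lower (0 of 15; adjusted p = 0.0156, and adjusted p = 0.592 with an estimated correlation). Immediate early genes were down (2 of 15, Junb at -0.92 ± 0.22 and Ier2 at -0.77 ± 0.19; 3 when adjusted over the list alone; adjusted p = 0.0194, and adjusted p = 0.592 with an estimated correlation). Outside the called lists Lef1, a transcription factor of the Wnt pathway, was higher (1.29 ± 0.20) and Rnf43 lower (-0.74 ± 0.19), and the engulfment receptor Megf10 was higher (1.22 ± 0.19). The count was 287 without p53-null mouse m2119, 770 without p53-null mouse m2493 (291 higher and 479 lower) and 301 without p21-null mouse m4116. Of 40 named calls, 18 were lost when some single mouse was left out, among them Trp53, B2m, Csn2, Fap, Junb, Ier2, Rnf43, Rpph1, Bcan, Dcpp3, Eno1b, BC018473, Xlr4c and Snora57. With only the groups compared, 15 of the 40 passed. Against untreated wild-type tumours, 14824 genes differed in p53-null and 15020 in p21-null tumours, in comparisons where genotype and library kit are confounded. On the protein-coding scale the counts were 9108 and 9405, and the balance turned. In p53-null tumours 14146 higher and 678 lower became 2044 and 7064, and in p21-null tumours 14330 and 690 became 1935 and 7470.

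Mdm2, which encodes the ubiquitin ligase of p53 and was chosen after its values were seen, stood at 260.8 TPM in untreated p53-null mouse m2119 and at 15.71 to 19.62 TPM in the other 3 mice of that group. The 13 other tested genes within 1 Mb of it (chromosome 10, 117688875 to 117710758) differed from the mean of those mice by a median of 3.76 log2, with Gm25709, which was listed at 0 in all 4 mice, counted as no difference. The genes named from this region were also chosen after their values were seen. Cct2, a chaperonin subunit, was at 3347 TPM against 198.9 to 251.5, and Nup107, of the nuclear pore, at 261.0 against 14.57 to 24.75. Lyz2, a lysozyme of macrophages that lies among them, was at 444.0 against 407.3 to 569.7. A stretch of chromosome 8 from Atp11a to Plpbp (12757014 to 27056132) held 43 of the 6520 genes used for comparing positions, with a median of 1.86 in the same mouse. It includes the growth factor receptor Fgfr1, likewise chosen after its values were seen, at 487.8 TPM against 60.69 to 117.1.

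**Figure D3:**
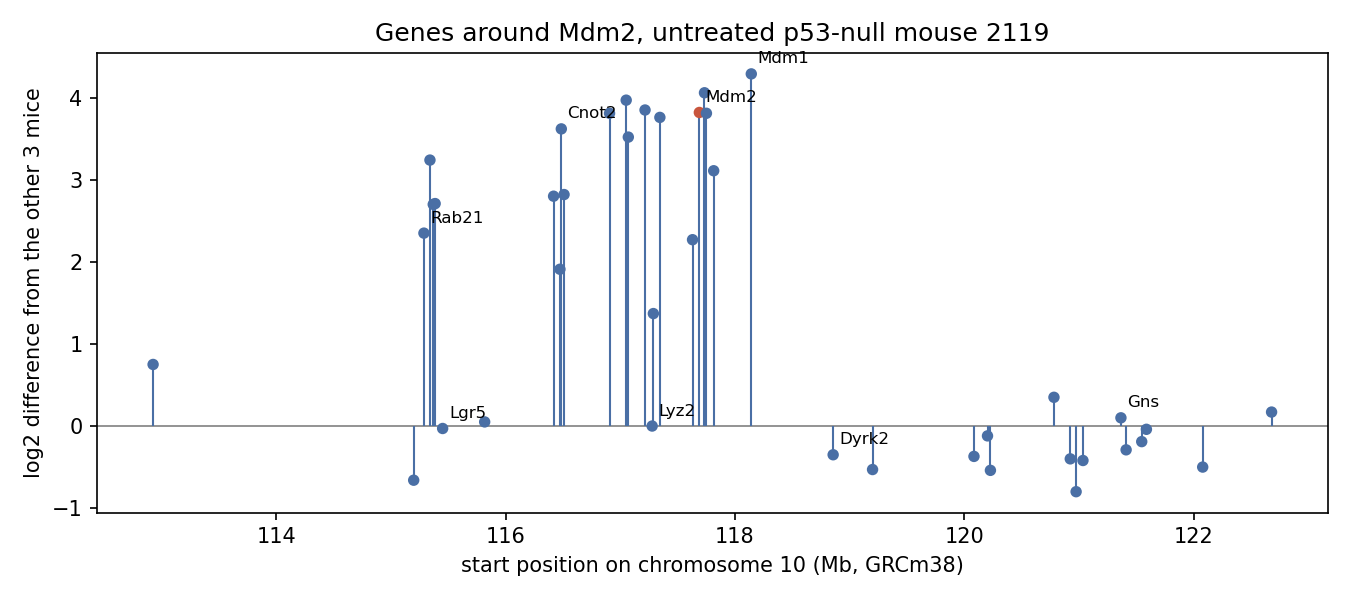
Genes along chromosome 10 by start position (Mb, GRCm38) with the log2 difference of untreated p53-null mouse m2119 from the mean of the other 3 mice of its group, 1 point per gene and Mdm2 in red. Mdm2 is at 3.82 and the 13 other tested genes within 1 Mb, including Gm25709, listed at 0 in all 4 mice and not drawn, have a median of 3.76.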

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

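The tests of the histone fall and of neutrophil markers in this part were chosen only after the results they address had been seen, while those of Mdm2 and of platelets were written before their values were computed, apart from the spread among the other mice beside Mdm2.

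In untreated p53-null mouse m2119, Mdm2 stood at 260.8 TPM, against 15.71 to 19.62 TPM in the other 3 mice of the group. Active p53 in this tumour might raise Mdm2, since p53 induces it, and would raise other targets too. The other 38 target genes measured had a median log2 difference of 0.14 from the other mice. Those mice, set against each other, were at -0.11 to 0.11, and the value lies under the 0.5 set beforehand, which excludes this explanation by that limit. A gain of the region is a candidate explanation: the 13 other tested genes within 1 Mb of Mdm2 (Gm25709 listed at 0 in all 4 mice) had a median difference of 3.76 log2, and those of the other mice, set against each other, were -0.32 to 0.35. Copy number was not analysed here, so the gain itself remains unmeasured.

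Histone transcripts fell with doxorubicin in wild-type tumours (17 of 18 genes), from a median of 307 to 116 on the protein-coding scale, and for 1 gene in p21-null and 0 in p53-null tumours, where the medians went from 1.5 to 0.801 and from 1.48 to 1.27. If libraries of the null genotypes could not measure histones, untreated ones would lie under 1 TPM. The higher median of the 2 null genotypes was 1.5, over that limit but near the floor, so it decides nothing. A second limit, of 25% of the wild-type level, was written after that value was seen. The null libraries hold 0.486%, so low capture by their kit stays possible, but kit and genotype cannot be told apart. Short noncoding RNA was also scarce in them, at 0.26% of TPM against 85.49% in wild-type libraries, so the gap is not particular to histones. At so low a level a fall in null tumours could hardly be seen, so its absence there says nothing about genotype. Fewer cells in S phase is a candidate explanation for the fall, as the mean of G1/S genes changed by -0.45 ± 0.18 (SE; exact permutation p = 0.013, n = 5 and 6 mice). For that list limma's camera had an adjusted p = 0.148 with an estimated correlation and fry an adjusted p = 0.081, and no single gene passed.

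Red blood cell transcripts fell in all 3 genotypes. Less blood of every kind in treated tumours might lower platelet transcripts as well. Their median log2 changes were 0.11, 0.02 and 0.19, with SE of the median of 0.25, 0.22 and 0.25. They lie above the limit of -0.5 set beforehand, which goes against this explanation by that limit. On the protein-coding scale they were 0.45, 0.04 and 0.2, so no fall of platelet transcripts was seen there either. Only 4 of 12 listed platelet markers passed the expression filter, most of them at low levels, where the log2(TPM + 1) scale compresses a fall. How large a loss of blood they could have shown was not tested, so a loss is not excluded. Neutrophil markers changed by 0.38, 0.44 and 1.09, but neutrophils entering the tissue could mask a loss of white blood cells carried in blood, which is left open.

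Sets of calls were compared with other splits of the same mice, counting the real split. For differences of responses, residuals were shuffled over the mice of both genotypes instead, which assumes an equal spread in all groups. The median SD over mice ranged from 0.158 to 0.293 log2 between groups. In wild-type tumours only the real split of 100 gave as many calls as the real 180 (highest other 79), and likewise for untreated tumours (491 against 116). Among shuffles the same held for the differences of p53-null (60 against 8) and p21-null responses from wild-type (65 against 1). With 100 draws no share under 1 of 100 could be seen, so chance looks unlikely here but is not excluded. For doxorubicin in p53-null tumours 13 of 100 splits gave as many as the real 330 (highest other 804), so chance cannot be excluded. In p21-null tumours 2 did (1537 against 3343), and for p21-null minus p53-null 4 did (153 against 3355). In the p53-null, the p21-null and the latter comparison, another draw thus gave more calls than the real one, and in the latter many times more. This points to a structure among these samples other than treatment, whose source was not tested.

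Responses differed between genotypes for 60 genes (p53-null minus wild-type), 65 (p21-null minus wild-type) and 153 (p21-null minus p53-null). On the protein-coding scale the counts were 111, 12 and 103. As deposited, median differences of lists were -0.67 for p53 targets and 1.30 for histones (p53-null minus wild-type). They were -3.53 for red blood cell genes and 1.27 for histones (p21-null minus wild-type), and 1.10 for p53 targets (p21-null minus p53-null). Both comparisons with wild-type cross the library kits, and histones are too low in null tumours to show a fall. Hbb-bt and Alas2, the red blood cell genes that passed for p21-null minus wild-type, did not pass on the protein-coding scale.

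Single mice stood apart from their group in 11 of 198 comparisons, where 5% are expected by chance. The number is thus close to that expected, and the values listed next may be chance. Trp53 was at 80.13 TPM in untreated p21-null mouse m4555 (others 101.51 to 108.95) and at 57.69 in treated p21-null mouse m4533 (79.1 to 97.45). Wnt1 was at 208.9 TPM in treated p53-null mouse m2688 (96.08 to 120.19). The mean log2 of p53 targets was 5.81 in treated p21-null mouse m4380 (5.37 to 5.56). In m4533 the mean of G2 and mitosis genes was 3.78 (4.93 to 5.83) and that of DNA repair genes 2.80 (3.34 to 3.84). Milk proteins averaged 2.64 in treated wild-type mouse m1188 (1.0 to 1.47). NK markers averaged 0.45 in treated wild-type mouse m1127 (0.24 to 0.3), 1.12 in untreated p53-null mouse m2119 (1.29 to 1.32) and 1.56 in untreated p21-null mouse m4383 (0.57 to 0.83).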

How the results depend on the processing

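No paired analysis was possible because no title number occurs in more than 1 group. Settings were set before the data were examined, with exceptions chosen only after the results were seen. These were fits of only the groups compared on the protein-coding scale, shared calls on that scale, and camera on that scale or with only the groups compared. The other exceptions were fry with only the groups compared, permutation of list means, and single genes with a mouse left out. The wild-type count of 180 was 318 and 110 with pseudocounts of 0.1 and 5, 959 with median-of-ratios scaling, 1083 with quantile normalization, 756 on the protein-coding scale, 423 with only the groups compared, and 1044 with both. The p53-null count of 330 was 196 and 498 with those pseudocounts and 1 with only the groups compared, as deposited and on the protein-coding scale (limma; 1332 and 1149 genes at an unadjusted p under 0.05). For p53-null minus wild-type, 60 became 102 with a pseudocount of 5, 173 with median-of-ratios scaling, 196 with quantile normalization, 111 on the protein-coding scale and 33 with only the groups compared. For p21-null minus wild-type, 65 became 9 and 163 with pseudocounts of 0.1 and 5, 35 with a filter at TPM 5, 12 on the protein-coding scale, 108 with only the groups compared and 11 with both. For p21-null minus p53-null, 153 became 94 with only the groups compared and 75 on the protein-coding scale as well. For untreated tumours, 491 became 324 with a pseudocount of 0.1, 264 on the protein-coding scale, 136 with only the groups compared and 67 with both.

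Shared rises of wild-type and p53-null tumours (19) were 58 with a pseudocount of 0.1, 83 on the protein-coding scale, 12 with all 40 tumours and 10 at 2-fold or more, and shared falls (3) were 10 on the protein-coding scale. Those of wild-type and p21-null (104 and 13) were 210 and 21 with a pseudocount of 0.1, 361 and 44 on the protein-coding scale, and 42 and 4 at 2-fold or more. Those of p53-null and p21-null (164 and 19) were 102 and 4 at 2-fold or more, and the falls 9 with a pseudocount of 0.1 and 29 with all 40 tumours. The interferon list in p53-null tumours had an adjusted p = 0.101 from limma's fry with only the groups compared. By exact permutation it had p = 0.00794, the smallest that 5 and 4 mice can give, and 0.23 after adjustment over 29 lists, so that test has little power to pass. Over all comparisons, 75 of camera's list calls did not pass with an estimated correlation, 61 did not with fry and 61 did not by permutation of list means. The list results left unchanged numbered 16, 30 and 30.

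Leaving out each mouse in turn gave 129 to 182 calls in wild-type, 166 to 547 in p53-null, 1006 to 1761 in p21-null, 26 to 76 for p53-null minus wild-type, 38 to 80 for p21-null minus wild-type, 124 to 228 for p21-null minus p53-null and 287 to 770 for untreated tumours. Directions turned only for changes near 0. Leaving out m1188 gave 0.0 for Trp53 in wild-type tumours (lowest -0.20, without m978), and leaving out m713 or m824 gave -0.01 or -0.0 for Wnt1 (highest 0.11, without m996). Cdkn1a in p53-null tumours was at -0.02 without m2119 and at most at 0.77, without m2688. For Cdkn1a in p21-null minus wild-type it was 0.01 to 0.12 without m1198, m996, m4116 or m4536, and at lowest -0.24, without m4555. Trp53 in p21-null minus p53-null was -0.05 to -0.01 without m2119, m2237, m2551, m2771 or m4555, and at highest 0.15, without m2769. Untreated Wnt1 was 0.01 with all 40 tumours, 0.10 without m2119, 0.09 without m881 and -0.51 without m2493.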

Other observations

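All tests in this part were chosen only after the results were seen, and they concern positions of genes in the genome. In p53-null tumours, neighbouring genes deviated together from their group in single mice. The correlation of deviations between genes 1 to 5 Mb apart, over 6520 genes with chromosomes 11 and 17 left out, averaged 0.178 ± 0.108 (SD, n = 9) in p53-null mice, with a range of 0.019 to 0.375. It was 0.055 ± 0.053 in p21-null mice (n = 14) and 0.036 ± 0.042 in wild-type mice (n = 11). Mouse m2119 had raised blocks on chromosome 10 around Mdm2 and on chromosome 8, and blocks in other mice were not tabulated. In the latter block, with genes chosen after their values were seen, Ikbkb, a kinase of NF-kB signalling, stood at 215.9 TPM against 23.91 to 44.27 in the other mice, the mitochondrial channel Vdac3 at 870.6 against 99.64 to 170.4, the acetyltransferase Kat6a at 56.5 against 5.4 to 11.18 and the polymerase Polb at 303.0 against 49.05 to 66.65.

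More regional gains and losses in p53-null than in p21-null tumours are a candidate explanation: their means differed by 0.123 (permutation p = 0.0013, n = 9 and 14 mice). A single mouse is unlikely to carry the difference, because without m2119, also left out of the median of its group, it was 0.09 (permutation p = 0.0049). The excess lies mostly in untreated tumours, with means of 0.264 in p53-null and 0.034 in p21-null mice (exact permutation p = 0.00794, n = 4 and 5). Treated mice overlapped, with means of 0.11 and 0.067 (exact permutation p = 0.252, n = 5 and 9), so a difference in treated tumours remains open. Sequencing of tumour DNA would test this.

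Some of the genes that differ most between untreated p53-null and p21-null tumours lie near Trp53 or Cdkn1a. DNA of the embryonic stem cells in which an allele was targeted might be carried along with it. Within 10 Mb of Cdkn1a 35 of 406 genes were called, 8.62%, above all of 6747 windows elsewhere (highest 7.14%, median 2.71%), with Scube3 and Rab44 among 34 genes within 1 Mb. How many of the 35 also stand in lists that differed between these tumours, such as the MHC class I list, was not tabulated. The 2 results may therefore not be independent. Around Trp53 the share was 5 of 333 genes, 1.5%, at percentile 11 of 8056 windows (median 2.7%, highest 7.51%), with Rpl26 and Tnfsf13os among those within 1 Mb. The rule used here asked for both loci to stand out, and by it the explanation is left open. The alleles belong to different genotypes, however, so the low share around Trp53 does not count against DNA carried along with Cdkn1a. Around Cdkn1a such DNA is a candidate explanation, but DNA sequence was not examined.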
